A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

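RNA from 9 cultures of budding yeast was measured, 1 array per culture: 6 of the haploid laboratory strain BY4742 (wild type, cultures 1 to 6) and 3 of BY4742 with LOS1 deleted (cultures 7 to 9). Per the labels' protocols, cells grew in rich glucose medium at 30 °C and 225 rpm to an OD600 of 0.5, were lysed with glass beads in a buffer that held cycloheximide, and the RNA was purified on columns from the cleared lysate. The arrays were Affymetrix Yeast_2 arrays, which carry probe sets for Saccharomyces cerevisiae and for the fission yeast S. pombe. Groups were taken from the sample descriptions. Per the labels' protocols, 3 isolates of each strain were grown and the 6 wild-type cultures were duplicates. The labels do not say which arrays share an isolate, so each array entered the tests as 1 replicate and every possible pairing was run as an alternative. P-values then measure the spread between cultures, and part of the wild-type spread is between cultures of the same isolate.

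The deposited values were log2 expression values per probe set, made by the authors with RMA, per the submitters' processing notes. RMA corrects background, quantile normalizes the arrays and summarises the probes of a probe set on the log2 scale. Its version was not given in the sources used here. Quantile normalization gives every array nearly the same distribution, so a change shared by most transcripts cannot be seen and each difference is relative to the other transcripts on the array. Values near the background are compressed, which makes changes of dim genes look smaller.

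Of 10928 probe sets, 7244 named 1 gene in the platform annotation, 1 named several and 3683 named none, among them 166 Affymetrix controls. An identifier matched S. cerevisiae assembly R64 for 5498 probe sets, and 12 symbols were updated through it. The other 1746 named probe sets were taken as S. pombe probe sets. Where a gene had over 1 probe set (47 genes), the one with the highest mean over the 9 arrays was kept, which left 5449 genes. For 114 of them the probe set was of a kind that can hybridise to near-identical transcripts. No genome coordinates are given, since the labels name no build. The S. pombe probe sets served as background: their 95th percentile was 4.67 on the means over arrays and 4.68 to 4.74 on single arrays. Where a group lay under this level on every array, the fold is given as a bound, with the dim group set to the background level. No scanner intensities were used here, and the number of arrays limits the precision.

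Differences (deletion minus wild type) were tested on the log2 scale with limma 3.58.1 (lmFit and eBayes, 2-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the 5449 genes and a threshold of 0.05 on adjusted p. Every adjusted p printed for a gene comes from this limma fit, unless another fit is named beside it. Exact 2-sided permutation tests of single values used all 84 assignments of the 9 arrays to groups of 6 and 3, so their smallest possible p was 0.0119. They take the 9 cultures as exchangeable, which would not hold if cultures of the same isolate resemble each other. Of 41 gene lists written before the data were examined, 40 had at least 3 measured genes and were tested. The list of mitochondrially encoded genes had none. LOS1, URA3, HIS3, LEU2 and LYS2, engineered in these strains, were left out of every list, and lists overlap. The list test was limma's camera, which asks whether a list's genes shift more than other genes, with its preset correlation of 0.01 between genes. Its version with an estimated correlation per list and fry were run beside it. In fry, PValue tests whether a list's genes move, on balance, one way, and PValue.Mixed whether they change in either direction. Neither compares the list with other genes. Each list's median was also placed among 10000 random lists of its size, matched on mean expression in 20 bins. Genes of a random list need not move together, so a list whose genes do can lie far out by this measure.

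The genes named were set by a rule fixed before the data were examined: the engineered loci, MET17 and the neighbours of LOS1; the 10 largest rises and 10 largest falls among genes past the threshold with no overlap between the groups, engineered loci excluded; up to 4 genes with the smallest p from each list past the threshold and up to 2 from each other list; and GCN4. Genes named outside it are said to be chosen after their values were seen.

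The alternatives were median centring of each array, repeated quantile normalization over the S. cerevisiae genes, leaving out genes under background, testing all probe sets, averaging a gene's probe sets, an intensity trend with a robust prior (statmod 1.5.0), array weights, a variance per group, an adjusted p of 0.01, a minimum of 1.5-fold, the 15 pairings of wild-type arrays, the 20 choices of 3 wild-type arrays, leaving out each array in turn and, for lists, estimated correlation and ranks. Added after the data were seen were a fit without wild-type cultures 1 and 4, a random block over the pairs 1 and 4, 2 and 5, 3 and 6, other groupings with these pairs averaged, the count of genes that passed in every leave-one-out fit and every pairing, and 5 further gene lists.

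The fit was tested on simulated data of this comparison, with the means and SDs of the 5449 genes and 200 of them changed. Over 10 draws it recovered 54.1% of changes of 0.25 on the log2 scale, 91.1% of changes of 0.5 and 99.1% of changes of 1, and 4.44% of its calls were false. Genes were drawn independently of each other, so this says nothing of false calls among lists of genes that move together. Arrays were drawn independently too, unlike cultures that share an isolate. The share of false calls therefore holds only for arrays that vary independently, and it may be higher in the real data.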

Results

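Gene expression was measured in yeast cells that lack LOS1 and in their wild-type parent. Los1 is the exportin that carries tRNA out of the nucleus. The series text asks which genes might act on lifespan downstream of Los1 when nutrients are not restricted, and the comparison it sets up is the deletion against wild type in rich medium. There were 6 wild-type arrays and 3 deletion arrays, each from its own culture, and values are log2 expression as mean ± SD unless stated otherwise.

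The deletion arrays stood apart from the wild-type arrays. Over 5449 genes, the correlation between arrays was 0.994 to 0.998 within wild type, 0.997 within the deletion and 0.986 to 0.993 between the groups. The first principal component held 54.5% of the variance, and the next held 14.7%. LOS1 and URA3, which differ by construction, were among the genes used for both measures. Part of the separation was therefore set by how the strains were made, and its size without these genes was not computed. The median gene had an SD of 0.0895 among wild-type arrays and 0.0704 among deletion arrays. Between 97.8% and 98.2% of the genes lay above the background level on each array. Of 10 array measures (medians, background, spike-in controls, 3′ to 5′ ratios of control transcripts), 2 had an exact permutation p under 0.05. The share of genes above background was 98.1 ± 0.0565% in wild type and 97.9 ± 0.148% in the deletion (exact permutation p = 0.0119), and the 3′ to 5′ log2 ratio of SPT15 was 1.41 ± 0.07 and 1.25 ± 0.05 (exact permutation p = 0.0238). The lowest p adjusted over the 10 measures was 0.119, which a single measure at the smallest possible exact p also gives, so the adjusted tests decide little. No arrays were copies of each other: of 10928 probe sets, at most 31 had equal values in any of the 36 pairs of arrays.

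LOS1 transcript (YKL205W) was at 11.11 ± 0.16 in wild type (n = 6) and under background in every deletion array, at 3.65, 2.76 and 3.18 in cultures 7, 8 and 9, so it was at least 84.1-fold lower (limma adjusted p = 4.79e-10). URA3 (YEL021W), which encodes an enzyme of uracil synthesis and is named in the titles of the deletion arrays, showed the opposite: it was under background in every wild-type array (3.06 ± 0.21, n = 6) and at 10.88 ± 0.04 in the deletion (n = 3), at least 72.8-fold higher (limma adjusted p = 2.06e-11). BY4742 lacks URA3, LEU2 and LYS2, so the groups differ at URA3 as well as at LOS1, and 0 arrays carried only 1 of these changes. LEU2 and LYS2 stayed near background in both groups, with differences of -0.01 and 0.08 (adjusted p = 0.947 and 0.789). HIS3, which is only partly deleted in BY4742, gave a clear signal and rose by 0.69 on the log2 scale in the deletion (adjusted p = 3.68e-04). MET17, a sulfur assimilation gene that is intact in this strain, rose by 0.66 (adjusted p = 0.00158). The neighbours of LOS1, ADD66 and EAP1, did not pass the test, with differences of -0.06 and -0.09 (adjusted p = 0.468 and 0.473).

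**Figure D1:**
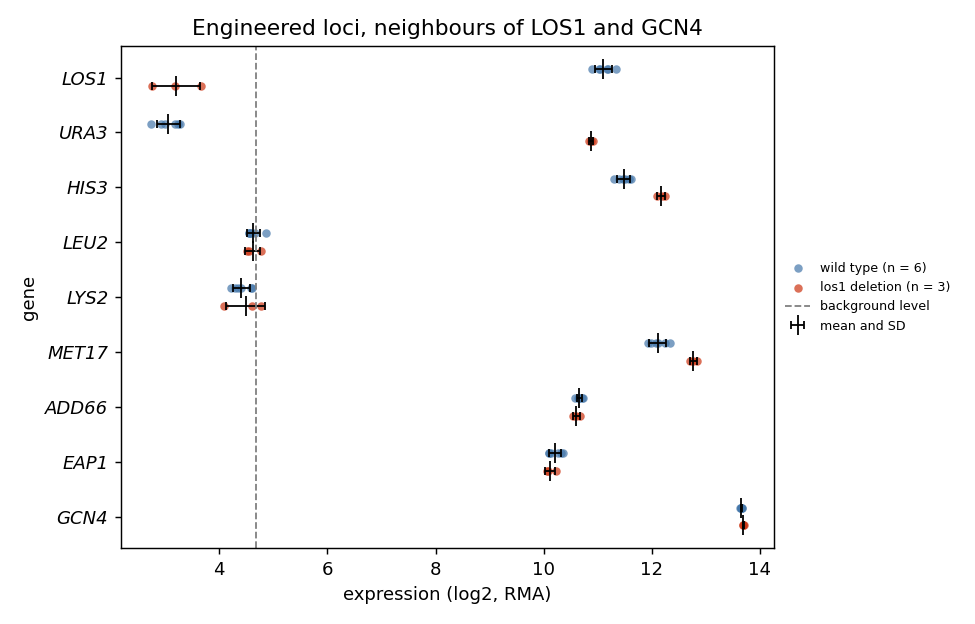
Expression (log2, RMA) of the engineered loci, MET17, the neighbours of LOS1 and GCN4 in each wild-type array (blue, n = 6) and each los1 deletion array (red, n = 3), with the mean and SD in black and the background level of 4.67 dashed. LOS1 lay under background in the 3 deletion arrays and URA3 in the 6 wild-type arrays.

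Besides these loci, the largest rises included genes of arginine synthesis, and the largest falls included genes of the phosphate regulon. The largest rises were in ARG1 and ARG4, the last enzymes of arginine synthesis, by 2.08 ± 0.14 and 1.36 ± 0.06 on the log2 scale (± SE, 4.23-fold and 2.57-fold), and in ARG7, a mitochondrial enzyme of ornithine formation, by 1.35 ± 0.08 (2.55-fold). CLD1, a phospholipase acting on cardiolipin, rose by 1.24, SRY1, a hydroxyaspartate dehydratase, by 1.00, and the uncharacterised YOL014W by 0.95. GGC1, the mitochondrial carrier of guanine nucleotides, ORT1, the mitochondrial ornithine carrier, and FMP23, a mitochondrial protein, rose by 0.88, 0.84 and 0.87. PCL5, a cyclin that directs the breakdown of the transcription factor Gcn4, rose by 0.87. Adjusted p for these 10 rises lay between 8.83e-07 (ARG4) and 0.0231 (YOL014W), and YOL014W lost its call in 7 of 21 alternative fits.

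The largest falls were in PHO89, a phosphate transporter, and PHO5, the secreted acid phosphatase, with log2 differences of -2.18 ± 0.33 and -2.18 ± 0.14 (± SE, 4.54-fold and 4.52-fold). MDH2, the cytosolic malate dehydrogenase of gluconeogenesis, fell by 1.94 on the log2 scale, and ADR1, an activator of glucose-repressed genes, fell by 1.32. HXK1, a hexokinase made when glucose is low, the hexose transporter HXT4 and MTH1, a repressor of hexose transporter genes, fell, with differences of -1.53, -1.27 and -1.34. PHM6 and SPL2, both of the phosphate response, fell, with differences of -1.34 and -1.26. The uncharacterised YNL034W, whose probe set can hybridise to near-identical transcripts, fell by 1.08. Its values of 5.03, 4.62 and 4.91 in deletion cultures 7, 8 and 9 lay near background, under it in culture 8, so the size of this fall is uncertain. Adjusted p for the 10 falls lay between 1.79e-05 (PHO5) and 0.0446 (HXT4). PHO89, HXK1, MTH1 and HXT4 varied most among wild-type cultures, with SDs of 0.57, 0.62, 0.59 and 0.62, since cultures 1 and 4 lay above the other wild-type cultures in each. Of 21 alternative fits, HXT4 lost its call in 12 (7 of the 9 that left out 1 array), MTH1 in 8 (4 of the 9) and HXK1 in 6 (2 of the 9).

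**Figure D2:**
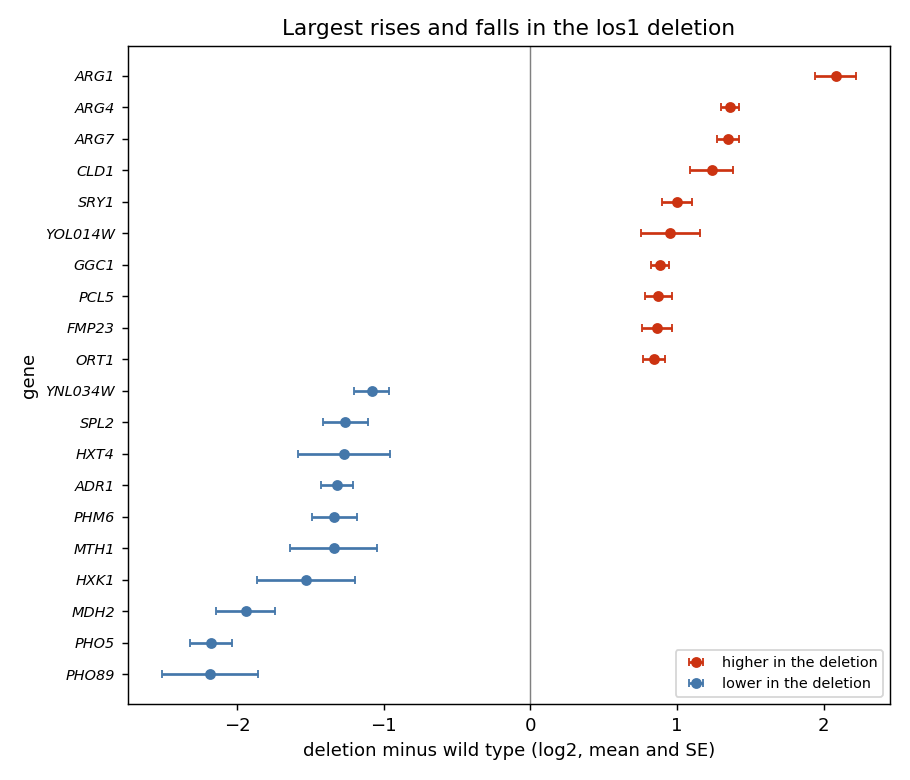
Log2 difference (deletion minus wild type, point and SE from limma) of the 10 genes with the largest rise and the 10 with the largest fall among genes whose groups did not overlap, engineered loci excluded. ARG1 rose by 2.08, and PHO89 and PHO5 both lay at -2.18.

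In all, 301 of 5449 genes passed the limma threshold, 143 higher and 158 lower in the deletion. Of these, 57 differed by at least 1.5-fold, 24 higher and 33 lower. Some of the genes counted as lower lay under background on every array of both groups. With genes under background left out of the fit, 301 genes passed, of which 296 also passed in the main fit. The groups did not overlap for 685 of the 5449 genes, and 296 of these 685 were past the threshold. For a single gene the probability of no overlap is 2.38% if the 9 cultures are exchangeable. Genes vary together and cultures may share an isolate, so the count does not measure an excess over chance. The split depended on scaling: after repeated quantile normalization 175 genes were higher and 126 lower. The count depended on the arrays: it was 126 without deletion culture 8 and 478 without wild-type culture 5, and 92 genes (54 higher, 38 lower) passed in every leave-one-out fit and under every pairing of the wild-type arrays.

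Of the 40 gene lists tested, 14 passed with camera's preset correlation, 9 of them upward and 5 downward. With an estimated correlation 2 of the lists passed, arginine synthesis and histidine synthesis. By fry, 9 lists moved on balance one way and 21 changed in either direction. Of the 84 assignments of the arrays, 23, the real one included, called 14 or more lists, and 2 of the others called 19. Those 2 each held 2 deletion arrays in the group of 3, and 10 of the 23 had only wild type in it. Such groupings still carry a part of the real difference, so the count of lists does not tell whether chance could give it.

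A part of the genes of amino acid synthesis rose in the deletion. Of 48 measured targets of Gcn4, the transcription factor that switches on amino acid synthesis when amino acids run short, 24 rose and 0 fell (33 rose and 2 fell when adjusted over the list alone). Their median difference was 0.28, above that of all 10000 matched random lists, and the list mean was higher in every deletion array than in any wild-type array (difference 0.35, exact permutation p = 0.0119, the smallest possible). Besides ARG1 and ARG4, the leading members were ARO3, which starts aromatic amino acid synthesis, and HOM3, which starts threonine and methionine synthesis, with rises of 0.58 and 0.56. Camera gave the list an adjusted p of 5.13e-26, and adjusted p = 0.0605 with an estimated correlation. GCN4 transcript itself, at 13.65 ± 0.01 in wild type and 13.69 ± 0.01 in the deletion, did not pass the test (difference 0.04, adjusted p = 0.525), although each deletion array lay above each wild-type array (exact permutation p = 0.0119).

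The rise was not equal across pathways. Of 8 measured arginine genes 5 rose (7 when adjusted over the list alone), with a median difference of 0.77 (adjusted p = 6.53e-13, and adjusted p = 0.038 with an estimated correlation). Of 6 histidine genes 4 rose (5 when adjusted over the list alone), led by HIS4 and HIS5 with 0.63 and 0.52 (median 0.30, adjusted p = 3.10e-06, and adjusted p = 0.038 with an estimated correlation). HIS1 and HIS2, which rose by 0.23 and 0.38, lost their calls in 5 and 10 of 21 alternative fits, of which 1 and 5 left out 1 array. Of 10 genes of leucine, isoleucine and valine synthesis 7 rose (7 over the list alone), among them ILV6 by 0.55, LEU4 by 0.51, LEU9 by 0.39 and ILV2 by 0.35 (median 0.33). Of 13 aromatic amino acid genes 8 rose (9 over the list alone), among them TRP3 by 0.39, TRP4 by 0.34 and ARO4 by 0.32 (median 0.27). Of 9 lysine genes 2 rose (5 over the list alone), LYS1 by 0.41 and ARO8, an aminotransferase, by 0.32 (median 0.17). For these 3 lists adjusted p was 5.90e-09, 1.32e-09 and 4.80e-05, and adjusted p = 0.067 with an estimated correlation for each.

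Of 24 genes of methionine synthesis and sulfur assimilation, 5 rose (9 when adjusted over the list alone), among them STR3 by 0.73, MET17 by 0.66, MET14 by 0.61 and STR2 by 0.32. The list's median was 0.17 (adjusted p = 6.15e-06, and adjusted p = 0.494 with an estimated correlation). Of 18 genes of serine, threonine, glutamate and proline synthesis, 3 rose (5 rose and 1 fell when adjusted over the list alone): HOM3, HOM2 by 0.36 and ASN1, an asparagine synthetase, by 0.29, a call lost in 6 of 21 alternative fits (2 of the 9 that left out 1 array). The serine gene SER3 had a difference of -0.36 that did not pass (adjusted p = 0.0618). That list's median was 0.06 (adjusted p = 0.0012, and adjusted p = 0.476 with an estimated correlation). Neither the 18 amino acid permease genes (adjusted p = 0.767) nor the 12 purine genes (adjusted p = 0.767) passed, with 0 members past the threshold in each, over all genes or when adjusted over the list alone.

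**Figure D3:**
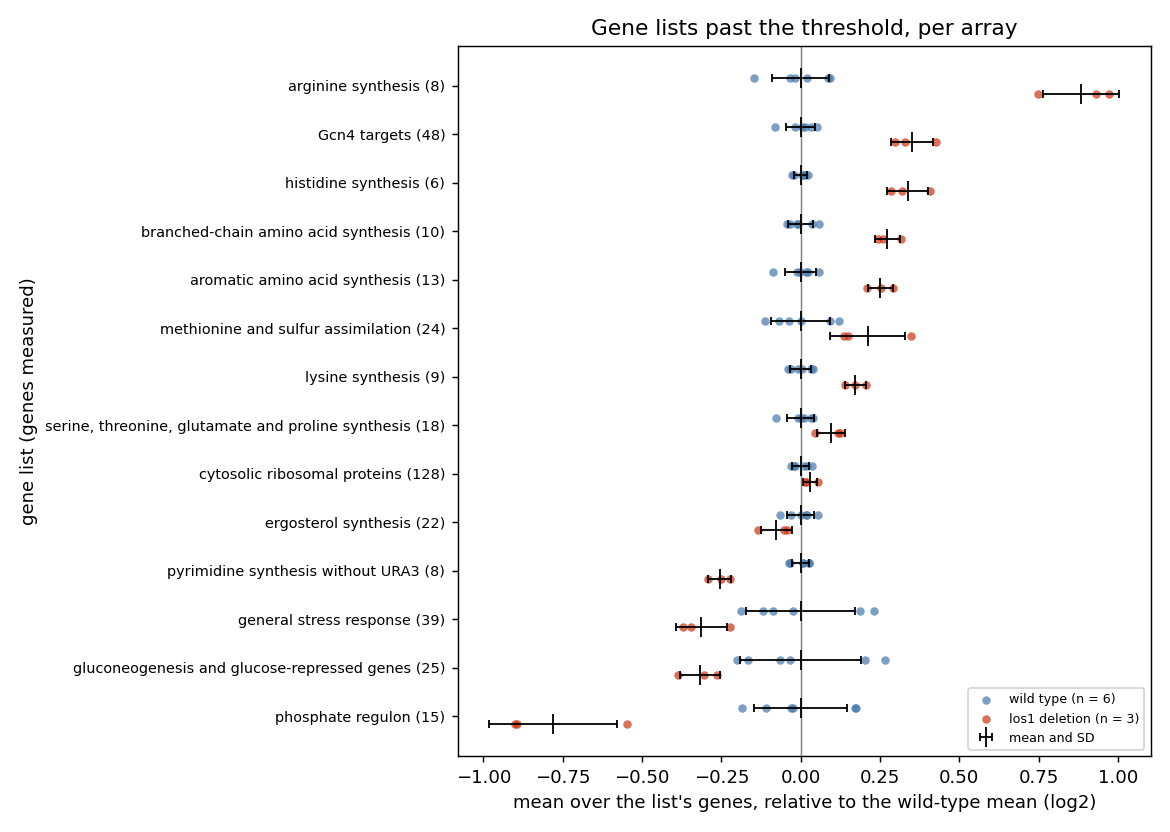
Mean log2 expression over the genes of each of the 14 lists past the camera threshold, relative to the wild-type mean, for each wild-type array (blue, n = 6) and each deletion array (red, n = 3), with the mean and SD in black and the number of genes measured in brackets. The groups were apart for arginine synthesis and for the phosphate regulon, and they overlapped for cytosolic ribosomal proteins and ergosterol synthesis.

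Genes that cells induce when phosphate runs short were lower in the deletion. Of 15 measured genes of the phosphate regulon, 12 fell and 0 rose (14 fell when adjusted over the list alone), with a median difference of -0.48. Besides PHO5, PHM6 and SPL2, the acid phosphatase PHO11 fell by 1.06 on the log2 scale, from 12.65 ± 0.14 (n = 6) to 11.59 ± 0.34 (n = 3), though its probe set can hybridise to near-identical transcripts. The list mean was lower in every deletion array than in any wild-type array (difference -0.78, exact permutation p = 0.0119). Camera gave an adjusted p of 6.53e-13, and adjusted p = 0.214 with an estimated correlation.

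Some genes repressed by glucose and some of the general stress response were also lower, 3 of 25 and 5 of 39, and both list means varied among wild-type cultures. Of 25 measured genes of gluconeogenesis and glucose repression, 3 fell and 0 rose (6 fell when adjusted over the list alone): MDH2, ADR1 and the galactokinase GAL1, which fell by 0.36 (adjusted p = 0.0489). GAL1 lost its call in 13 of 21 alternative fits, 7 of them without 1 array and another with the wild-type cultures as paired blocks (adjusted p = 0.0598). HXT7, a high-affinity hexose transporter, had a difference of -1.47 that did not pass (adjusted p = 0.0893). The list's median was -0.11 (adjusted p = 0.0277, and adjusted p = 0.754 with an estimated correlation), and its adjusted p was 0.0584 without wild-type culture 1, 0.0679 on ranks and 0.0999 without wild-type cultures 1 and 4, a fit added after the data were seen. After repeated quantile normalization its median was only -0.03 (adjusted p = 0.0778). Of 39 stress genes, 5 fell and 0 rose (10 fell when adjusted over the list alone), among them HXK1, the secreted glycoprotein YGP1 (-0.62), the aldehyde dehydrogenase ALD3 (-0.33) and MSC1 (-0.28), of which ALD3 and MSC1 lost their calls in 7 and 12 of 21 alternative fits. That list's median was -0.19 (adjusted p = 1.86e-05, and adjusted p = 0.494 with an estimated correlation). Relative to the wild-type mean, the glucose-repressed list lay at 0.26 and 0.20 in wild-type cultures 1 and 4. It lay at -0.03 to -0.20 in the other wild-type cultures and at -0.26 to -0.39 in the deletion cultures. The 19 genes of glycolysis and fermentation did not pass as a list (adjusted p = 0.185), where HXK1 was the 1 gene past the threshold (2 fell when adjusted over the list alone).

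Pyrimidine synthesis was lower at 3 of its 8 measured genes. URA1, the dihydroorotate dehydrogenase, fell from 13.18 ± 0.11 (n = 6) to 12.12 ± 0.07 (n = 3), a difference of -1.06 (adjusted p = 1.28e-05). URA4, the dihydroorotase, fell by 0.54 (adjusted p = 8.49e-05) and URA10, an orotate phosphoribosyltransferase, fell by 0.33 (adjusted p = 0.00342). The other 5 genes had differences between -0.12 and 0.06 and did not pass, and the count was also 3 when adjusted over the list alone. The list, from which URA3 was left out, had an adjusted p of 0.00361, and adjusted p = 0.067 with an estimated correlation. On ranks its adjusted p was 0.126.

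A further 2 lists passed without a single member past the threshold. The 128 cytosolic ribosomal protein genes had a median difference of 0.02 (adjusted p = 0.00156, and adjusted p = 0.898 with an estimated correlation), led by RPS10B with 0.11. The 22 ergosterol genes had a median of -0.06 (adjusted p = 0.0309, and adjusted p = 0.754 with an estimated correlation), led by ERG11 with -0.21. Both calls were lost without deletion culture 8 (adjusted p = 0.103 and 0.194), and the ribosomal call also after repeated quantile normalization (adjusted p = 0.39). In both lists 0 members passed when adjusted over the list alone.

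Genes closest to the function of Los1 did not pass as lists. None of 26 measured genes of tRNA export and maturation passed, and their median difference was -0.02 (adjusted p = 0.942). The smallest p in that list belonged to PUS1, a tRNA pseudouridine synthase, with 0.16 (adjusted p = 0.0644), and MSN5, another exportin, had -0.09 (adjusted p = 0.31). None of 19 aminoacyl-tRNA synthetase genes (adjusted p = 0.789) and none of 17 genes of the Gcn2 pathway and translation initiation control (adjusted p = 0.789) passed. Of 23 genes of RNA polymerase III and its factors, BRF1, a subunit of its initiation factor, rose by 0.19 (list adjusted p = 0.18), a call lost in 11 of 21 alternative fits. In these 4 lists the counts were the same when adjusted over the list alone.

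Of 28 genes of nutrient signalling and lifespan, 2 rose (2 rose and 1 fell when adjusted over the list alone), IDH2, a subunit of isocitrate dehydrogenase, by 0.27 and SIP4, an activator of gluconeogenic genes, by 0.50. As a list they did not shift relative to other genes (adjusted p = 0.767), while fry's test for change in either direction gave an adjusted p of 5.29e-06. IDH2 and the other subunit IDH1, with 0.31, were the 2 genes that rose among 48 of respiration and the TCA cycle (list adjusted p = 0.503, and the same 2 over the list alone). Of 21 alternative fits, the calls of IDH2, SIP4 and IDH1 were lost in 7, 11 and 11, of which 3, 7 and 6 left out 1 array. The 60 genes of ribosome biogenesis, 33 of the proteasome, 21 of autophagy and 26 of heat shock proteins and chaperones had 0 members past the threshold, and the lists had adjusted p of 0.767, 0.942, 0.767 and 0.503. The same held for mitochondrial ribosomal proteins (55 genes, adjusted p = 0.0701), the DNA damage response (24 genes, 0.0905), genes of the G1/S and of the G2/M and M/G1 parts of the cell cycle (22 and 21 genes, 0.153 and 0.594), histones (9 genes, 0.916) and haploid and pheromone response genes (16 genes, 0.889). Adjusted over the list alone, 0 members of these 10 lists passed.

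Single members passed in other lists that did not. In the iron regulon (18 genes, list adjusted p = 0.128), LSO1 passed the test (adjusted p = 0.00755) but lay under background in all 3 deletion arrays and in 5 of 6 wild-type arrays, so no fold is given. Of 26 oxidative stress genes (list adjusted p = 0.381), the peroxiredoxins PRX1 and TSA2 fell, with differences of -0.31 and -0.38, and 1 gene rose. Among 9 genes of flocculation and filamentous growth (list adjusted p = 0.224), PGU1, a pectin-degrading enzyme, fell by 0.90, and among 15 cell wall genes (list adjusted p = 0.381), the mannoprotein CWP1 fell by 0.84. The calls of PRX1, TSA2, PGU1 and CWP1 were lost in 6, 11, 4 and 5 of 21 alternative fits, of which 2, 6, 1 and 2 left out 1 array. NDT80, an activator of middle meiotic genes, rose by 0.52 among 18 genes of meiosis and sporulation (list adjusted p = 0.767). Adjusted over the list alone, the iron, oxidative stress, flocculation, cell wall and meiosis lists had 0, 1, 1, 1 and 2 genes that rose and 2, 2, 2, 3 and 4 that fell. Markers of mating type did not pass: the 7 a-cell markers and 5 alpha-cell markers had 0 members past the threshold (0 and 1 when adjusted over the list alone) and list adjusted p of 0.232 and 0.735.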

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

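All of the tests in this part were chosen before the results were seen, except the test of probe sets outside the named S. cerevisiae genes.

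Among wild-type cultures, 1 culture lay far from the other 5 in 5 of 160 genes and list means examined, and chance alone marks about 1 in 20 groups. HIS2 was at 10.57 in culture 4 against 10.81 to 10.93 in the others. RPS10B was at 12.78 in culture 5 against 12.62 to 12.68, and GAL1 was at 7.98 in culture 5 against 8.24 to 8.37. LSO1 was at 4.84 in culture 3 against 4.41 to 4.56. The mean of the autophagy list was 9.20 in culture 1 against 9.13 to 9.15.

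Of the probe sets left out of the comparison, 7 with no gene name were above background and at least 1.5-fold higher in the deletion at an adjusted p under 0.05 in a limma fit over all 10928 probe sets. The 3 Affymetrix control probe sets for URA3 were under background in every wild-type array and rose by at least 6.33, 6.16 and 5.76 on the log2 scale, beside at least 6.19 for the URA3 gene probe set. Probe sets 1777097_at, 1777793_at, 1778878_s_at and 1779914_at rose by 1.67, 1.63, 0.94 and 0.66. At least 1.5-fold lower were 1779784_at and 1776865_at, with differences of -1.25 and -0.74 (limma adjusted p = 0.0334 and 6.84e-04). Probe set 1776828_at also passed toward lower values (limma adjusted p = 0.0399), but its mean of 4.50 in the deletion was under background, so no fold is given. The genes of the probe sets given by number are not named in the annotation used here. In the same fit 1 of 1746 S. pombe probe sets passed, with a difference of 0.27.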

How the results depend on the processing

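The fit without wild-type cultures 1 and 4 and the random block were chosen after the results were seen, and the other alternatives before the data were examined. No named gene or list past the threshold reversed direction in the alternatives run for it. Differences that were not past it changed sign in 10 results of 3 genes (LEU2, LYS2 and EAP1) and direction in 28 results of 12 lists; LEU2 was at 0.01 after centring and 0.09 after quantile normalization. The balance of calls also turned, from 143 higher and 158 lower to 175 and 141 after centring and 175 and 126 after quantile normalization. LOS1, URA3, HIS3, MET17, ARG1, CLD1, PHO5, MDH2, ADR1, HOM3, LEU4, HIS4, STR3, URA1 and URA4 stayed past the threshold under every alternative run for single genes. They were 15 of the 62 called genes among the 120 named. LOS1 and URA3 kept their calls in all 21 alternatives run for them. Over the other 118 named genes and their alternatives, 2231 results stayed on their side of the threshold, 187 lost the call and 57 gained it. Of the 301 genes, 281 passed after centring (316 called) and 263 after repeated quantile normalization (301 called). No paired analysis was possible because the groups share no culture numbers. The precision is limited by 3 deletion arrays, and the levels of LOS1 and URA3 in the groups that lack them are known only as under background.

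The number of genes past the threshold was 169 (89 higher, 80 lower) with all probe sets tested, 498 (235 and 263) with array weights, 78 (36 and 42) with a variance per group, 110 (58 and 52) at an adjusted p of 0.01 and 57 (24 and 33) with at least 1.5-fold. Leaving out 1 array gave 126 to 478 genes, 69 to 216 higher and 57 to 262 lower. The count moved by over 1.5 times without wild-type culture 4 (183) or 5 (478) and without deletion culture 7 (170), 8 (126) or 9 (148), and the lower genes also without wild-type culture 1 (99). The 15 pairings of wild-type arrays gave 129 to 447 genes, at least 66 higher and 61 to 263 lower, and all 14 lists passed under each. The pairing of 1 with 4, 2 with 5 and 3 with 6, hinted at by correlated deviations (0.47, 0.27 and 0.09), gave 143 genes, and as a random block 246. The 20 choices of 3 wild-type arrays gave 72 to 572 genes, at least 39 higher and 31 to 369 lower. Without wild-type cultures 1 and 4 there were 146 genes, 73 each way. A stricter adjusted p or a minimum fold can by construction only lower the count. Leaving out arrays moved it both ways, and the cause of the other changes was not tested.

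With an estimated correlation 2 of the 14 lists passed. The adjusted p was then 0.0605 for Gcn4 targets, 0.067 for lysine, branched-chain and aromatic synthesis and for pyrimidine synthesis, 0.214 for the phosphate regulon, 0.494 for methionine and sulfur and for general stress, 0.476 for serine, threonine, glutamate and proline, 0.754 for glucose-repressed and ergosterol genes and 0.898 for ribosomal proteins. The glucose-repressed list lost its call after repeated quantile normalization (0.0778), on ranks (0.0679) and without wild-type cultures 1 and 4 (0.0999), and leaving out 1 array gave 0.00921 to 0.0584, the latter without wild-type culture 1. The ribosomal protein list lost it after quantile normalization (0.39) and without cultures 1 and 4 (0.077), with 0.000255 to 0.103 when 1 array was left out (0.103 without deletion culture 8). The ergosterol list lost it without cultures 1 and 4 (0.0700), with 0.0166 to 0.194 when 1 array was left out (0.194 without deletion culture 8, 0.0659 without wild-type culture 6). The pyrimidine list lost it on ranks (0.126). Lists not past the threshold gained a call in 9 of their alternatives and kept their side in 433. The cause was not tested.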

Other observations

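The 5 gene lists of the next paragraphs, the comparison of arginine genes with other Gcn4 targets, the count of genes over other groupings of the arrays, the groupings with wild-type arrays averaged in pairs, the removal of culture variation from general stress genes and from the whole pyrimidine list, and the tests of normalization and of the URA3 marker were chosen only after the results were seen. The other tests that remove variation between cultures and the count of lists over other groupings were set before those tests were run.

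Most genes past the threshold, 232 of 301, belong to none of the 40 lists. The same holds for most genes tested: 4528 of 5449 lie outside the lists and the engineered loci. Of 29 carriers that move metabolites across the inner mitochondrial membrane, 6 rose and 0 fell: GGC1 and ORT1, the carriers YMC1 and YMC2 by 0.45 and 0.52, the dicarboxylate carrier DIC1 by 0.45 and the oxaloacetate carrier OAC1 by 0.36 (2 of the 29, ORT1 among them, are also Gcn4 targets; list adjusted p = 0.00249 over 45 lists, and adjusted p = 0.475 with an estimated correlation). Of 27 genes of iron-sulfur cluster assembly, 6 rose and 0 fell, among them the scaffolds ISU2 and ISU1 by 0.54 and 0.28, the sulfhydryl oxidase ERV1 by 0.41 and the ferredoxin YAH1 by 0.28 (list adjusted p = 0.0014, and adjusted p = 0.349 with an estimated correlation). In both lists the mean was higher in every deletion array (exact permutation p = 0.0119), though the medians were only 0.02 and 0.06. These lists were written around genes already seen to rise, so their p-values are not independent evidence.

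The glycine cleavage genes GCV1, GCV2 and GCV3 rose by 0.34, 0.50 and 0.34 among 9 one-carbon genes (list adjusted p = 0.0995). In NAD synthesis BNA1 and NRK1 rose by 0.66 and 0.31 and BNA2 fell by 0.81 (15 genes, list adjusted p = 0.887). Among 13 glycogen genes the debranching enzyme GDB1 and the phosphorylase GPH1 fell, with differences of -0.66 and -0.72, and GLG2, a glycogen primer, rose by 0.20 (list adjusted p = 0.0808). The riboflavin genes RIB4 and RIB5 moved apart, with differences of -0.57 and 0.56. ARG80, a regulator of arginine genes, rose by 0.40, while the arginine breakdown genes CAR1 and CAR2 had differences of 0.01 and 0.12 that did not pass (adjusted p = 0.965 and 0.421). These genes were chosen after their values were seen.

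Of the 84 splits of the 9 arrays into 6 and 3, the real one called 301 genes and the highest other 47. For lists, 23 of the 84 splits gave at least the 14 of the real one, and the highest other gave 19. Every other split puts deletion and wild-type arrays in the same group. The strain difference then widens the spread within groups, which can lower the number of genes called. Such splits can also carry a part of that difference: 10 of the 23 had only wild type in the group of 3. Splits with 1 deletion array in the group of 3 hold equal shares of deletion arrays in both groups, and they called 0 to 15 lists. Per the protocols the wild-type cultures were duplicates of isolates, so the arrays may not be exchangeable. Chance is therefore neither excluded by the count of genes nor shown by the count of lists. With wild-type arrays averaged in the pairs 1 and 4, 2 and 5, 3 and 6, only 10 splits exist, too few for a share under 0.05: the real one gave 143 genes and the highest other 0, and for lists 14 and 15 (1 and 4 splits gave as many).

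The rise of Gcn4 targets was weighed against normalization, culture variation and the URA3 marker. Repeating the normalization or centring the arrays left at least 99.9% of the list's median difference. The deposited values were already quantile normalized, and the median difference over all genes moved only from -0.012 to 0.0002 and 0.005. These steps could therefore hardly remove the rise, and they do not test the authors' normalization. A shift common to genes of similar expression would also move the matched random lists, and the list's median lay above all 10000 of them. The cytosolic ribosomal proteins reached the same place among their random lists. Their median was only 0.02, and their list means overlapped between the groups (exact permutation p = 0.179). This place alone is therefore weak support for a list whose genes move together. The main axis of variation among wild-type cultures held 41.5% of their variance over genes outside the lists, and removing it left a mean difference of 0.39 (0.35 before), with every deletion array still above every wild-type array. The list fell along this axis in wild type, and the deletion arrays scored on its positive side (2.73, 8.63 and 4.69). The removal could therefore hardly lower the rise, and variation off this axis was not removed. The LOS1 deletion and the URA3 marker cannot be told apart, because 0 arrays carry only 1 of them, and uracil synthesis restored by URA3 could also alter amino acid synthesis. An effect of the LOS1 deletion on Gcn4 targets therefore stays a hypothesis, and a small rise of GCN4 transcript (0.04, exact permutation p = 0.0119) is not excluded.

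The fall of URA1, URA4 and URA10 was weighed against culture variation and the URA3 marker. These are the members of the 8-gene pyrimidine list that passed, so they were chosen for their fall. Removing the axis left them a mean difference of -0.61 (-0.64 before) and the whole list one of -0.23 (-0.26 before), with the groups apart in both (exact permutation p = 0.0119). The marker cannot be told apart from the deletion here either (0 arrays carry only 1 of them), and since these genes are known to be switched on when uracil precursors build up, as they can in cells without URA3, the marker is a candidate explanation that stays open.

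The lower mean of glucose-repressed genes was weighed against variation between cultures. Removing the axis moved the list's difference from -0.32 to -0.14 and the groups then overlapped (exact permutation p = 0.0357 before and after). Part of the fall may be variation that wild-type cultures also show. The deletion arrays scored 2.73, 8.63 and 4.69 on the axis, against -5.67 to 7.71 in wild type. The removal may therefore also take away an effect of the strain difference, and it cannot tell these apart. The same removal moved the general stress list from -0.31 to -0.17, and its groups then overlapped too (exact permutation p = 0.0357 before and 0.0595 after). What remained is open between the deletion, the marker and culture conditions. The phosphate regulon kept a difference of -0.70 (-0.78 before) with the groups apart after the same removal. However, the SD of its mean among wild-type cultures only went from 0.147 to 0.124, against 0.192 to 0.077 for the glucose-repressed list. The axis thus holds little of how the phosphate list varies between cultures, and its removal cannot decide whether such variation explains the fall.

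Arginine genes had a higher mean difference than the Gcn4 targets outside arginine synthesis. The gap between the mean of 8 arginine genes and that of these 42 targets, of which 20 rose, was 0.61 in the deletion arrays relative to wild type, at least 0.52 in each of them and at most 0.07 in any wild-type array (exact permutation p = 0.0119). Only 6 of the 8 are in the Gcn4 list, and for these the gap was 0.64 (exact permutation p = 0.0119). This is a difference found and tested on the same data. Whether arginine genes respond to something besides Gcn4 was not tested. Arginine and uracil synthesis share carbamoyl phosphate as a precursor, and whether the URA3 marker plays a part was not tested.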
